A study of Mus musculus with 12 samples.

How the data were processed

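Gene expression was measured on Affymetrix whole-transcript arrays in 12 mouse brain cell cultures, 1 array per culture. Per the labels, 9 cultures were grown from glioblastomas, 3 from each of 3 transgenic mouse lines, and 3 were neural stem cell (NSC) cultures, 1 from each line. Groups were taken from the labels, which describe the tumour cultures as independent biological replicates. The labels do not say whether each came from another animal, so p-values measure the spread between these cultures. The NSC cultures carry no replicate number in the labels and were named by mouse line.

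The deposited values are log2 probe set summaries that the authors made with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA subtracts background, sets the arrays to a common distribution and summarises the probes of each probe set. Its software version, its annotation release and the summarisation level are not given in the sources used here. Because quantile scaling makes the distributions alike, a change shared by most genes cannot be seen in such values. The array medians lay between 7.60 and 7.66 on the log2 scale. Arrays hold no read depth, and the number of arrays limits the precision. Signal over background was not measured. Y-linked transcripts in the cultures without them read 4.26 to 5.56, and the spermatid genes Prm2, Tnp1, Tnp2 and Odf1, taken as absent from all 12 cultures, read 5.60 to 7.42. Background thus differs between probe sets. In all texts, a called difference of a gene with its lower mean at or below 7.42 is to be read as a lower bound, with no order among such differences. The values were used as deposited, with no further background step, scaling or filter on low values. No column of the table lacked a sample.

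The table held 28270 probe sets, of which 23397 were listed in the platform annotation, dated 2016. Exactly 1 gene symbol was given for 21780 probe sets (19934 distinct symbols), several for 1617, and 4873 were not listed. Only the 21780 probe sets with 1 symbol were tested and named, each as its own measurement. The gene identifiers of 21689 of these matched the RefSeq gene table of GRCm38.p6 and 91 did not, and 0 symbols had to be updated. That table was used for names, for the chromosome of each gene and for the order of genes along it. The genome build behind the array annotation is not given in the sources used here, so no coordinates are printed.

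Tests were run in R 4.3.3 with limma 3.58.1, using lmFit and eBayes with a constant variance prior, two-sided, with Benjamini-Hochberg adjustment over all 21780 probe sets. A probe set was called at an adjusted p under 0.05. The 3 pairwise comparisons of tumour groups and the moderated F test of any difference among them were fitted on the 9 tumour arrays. The comparison of tumour cultures with NSC cultures was fitted on all 12 arrays, as the mean of the 3 tumour group means minus the NSC mean. Differences are given on the log2 scale as the estimate ± its standard error from limma, and group levels as mean ± SD.

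Fixed gene lists were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. Of 28 lists holding 429 genes, 400 genes were measured, 2 of them found through an older symbol (Chil1 and Ero1a). The list of sex-linked genes served only to describe the cultures, which left 27 lists to test. For each list the members that rose, fell or did not pass were counted after adjustment over all probe sets and also adjusted over the list alone, where a rise means a higher value in the first group named. Camera with a correlation estimated for each list, and fry, were run as alternatives.

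The similarity of arrays was measured by Euclidean distance over the 21780 probe sets and tested by exact permutation of the group labels. For the probe sets called between tumour groups, the difference between the NSC cultures of the same mouse lines was computed. With 1 NSC culture per line it carries no test, and its median was placed among 10000 random lists of equal size, matched on mean expression in 20 bins and carrying the same number of signs.

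The groups, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined, apart from those said to be chosen afterwards. The rule took, among called probe sets whose arrays did not overlap between both sides, the 10 genes with the largest rise and the 10 with the largest fall for mGC1_GFAP against mGC3_CNP and for tumour against NSC, and 5 and 5 for each of the other pairwise comparisons. A gene with several probe sets counted once, by the smallest p. Predicted genes (Gm, Rik, LOC, Mir and Snor names) were counted and not named. Where fewer than 5 genes passed in a direction, the smallest unadjusted p would have followed, said to fail, which did not occur. Gfap, Nes, Cnp, Pdgfra, Pdgfb, Cdkn2a and Cdkn2b were named in every comparison whatever their value. Trp53, also fixed, is not analysed here, because no probe set carries its symbol alone, which left 7 of the 8 fixed genes. Up to 4 members with the smallest p were named from each list described. A few other genes, said to be chosen after their values were seen, fall outside the rule.

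The calling of single probe sets was tested on simulated data for 21780 probe sets with the group sizes of the study and 200 probe sets changed. Noise was drawn independently for each probe set, while real probe sets can vary together, so the shares need not hold for the real data. For changes of 0.5, 1 and 2 on the log2 scale, 44.8%, 89.6% and 98.5% were recovered for mGC1_GFAP against mGC3_CNP, and 61.2%, 100% and 100% for tumour against NSC. False calls made up 3.73% and 3.87% of the calls in these comparisons. The recovered shares were 49.3%, 88.1% and 97.0% for mGC1_GFAP against mGC2_NES, with 6.59% false calls, and 64.2%, 95.5% and 98.5% for mGC2_NES against mGC3_CNP, with 4.97%.

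The alternatives covered a filter on low values, centring of each array, a further quantile normalization, a trended and robust variance prior, array weights, all probe sets of the table, 1 value per gene, other sets of arrays in the fit, the replicate number or mouse line as a block, and leaving out each array in turn. A covariate for Y-linked transcripts, leaving out genes on the sex chromosomes and subtracting the NSC difference of the mouse lines were added after the values were seen. The subtraction is given without a test, because each line had 1 NSC culture.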

Results

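The study asked how the cell of origin shapes glioblastoma cells. The tumours were made in mice lacking Arf, a tumour suppressor encoded at Cdkn2a, that carry tv-a, the receptor for an avian retrovirus. In such lines a promoter decides which brain cells make the receptor and can be infected. The G/tv-a line uses the promoter of Gfap, an astrocyte and stem cell gene, the N/tv-a line that of Nes, a progenitor gene, and the C/tv-a line that of Cnp, an oligodendrocyte lineage gene. Chicken cells releasing a virus that encodes the growth factor PDGFB were injected into adult brain. From the tumours, 3 cultures per line were grown, named mGC1_GFAP (G/tv-a), mGC2_NES (N/tv-a) and mGC3_CNP (C/tv-a). Another 3 cultures, 1 per line, were NSC from the subventricular zone of adult mice. All 12 cultures were grown adherently in stem cell medium without treatment, and each was measured on 1 array. Each tumour group came from 1 mouse line, so that origin and line coincide in the tumour cultures.

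Transcripts of the Y-linked genes Eif2s3y, Kdm5d and Uty, with a mean log2 value above 7, were present in 2 of 3 mGC1_GFAP, 2 of 3 mGC2_NES, 0 of 3 mGC3_CNP and 2 of 3 NSC cultures. The G/tv-a NSC culture had both Xist, the X inactivation transcript, at 11.9 and a Y-linked mean of 8.39. The mGC2_NES replicate 2 culture had Xist at 9.27 without Y-linked transcripts.

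Tumour and NSC cultures stood far apart, and tumour cultures lay closer to others of their own origin than to those of another. The mean distance between a tumour and an NSC array was 101.6, against 38.4 between NSC arrays. Among tumour arrays it was 48.4 between groups and 39.8 within groups. Of the 280 divisions of the 9 arrays into 3 groups of 3, only the real one gave a difference as large as 8.67 (exact one-sided permutation p = 0.00357, the smallest the design allows). The mGC1_GFAP and mGC2_NES groups were furthest apart at 52.4, against 45.7 for mGC1_GFAP and mGC3_CNP and 47.2 for mGC2_NES and mGC3_CNP. Averaged over groups, tumour arrays lay at 100.9 from the NSC culture of their own line and at 102.0 from the others (exact one-sided permutation p = 0.167, the smallest that 6 assignments allow). The groups did not agree in this. All 3 mGC1_GFAP and all 3 mGC2_NES arrays were closest to the NSC culture of their own line, while all 3 mGC3_CNP arrays were furthest from theirs, at 101.7 on average against 99.7 for the G/tv-a and 100.1 for the N/tv-a culture. The C/tv-a culture was the furthest NSC culture for all 9 tumour arrays.

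**Figure D1:**
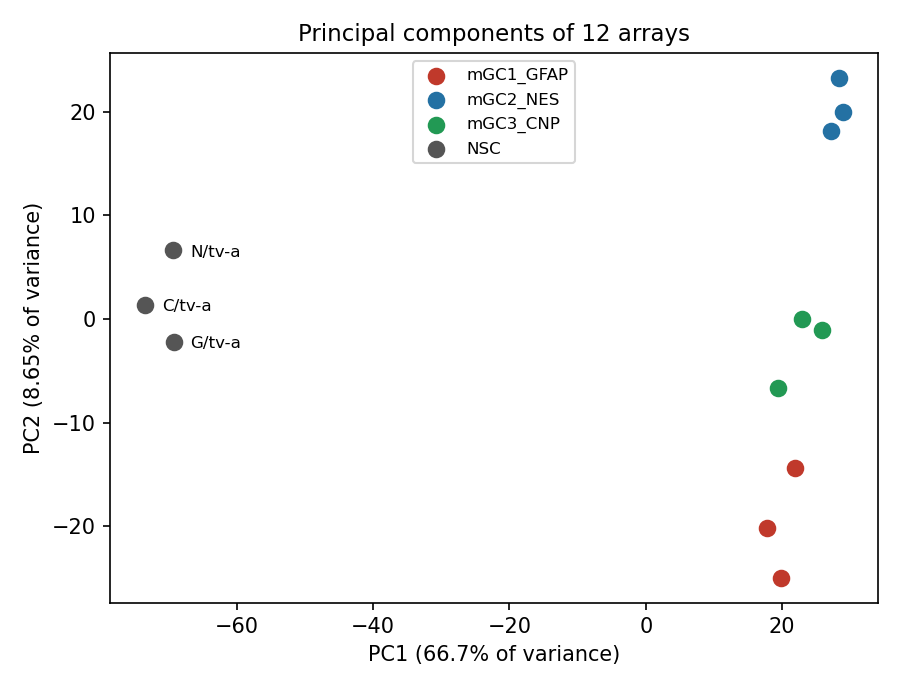
First and second principal components of the 12 arrays over probe sets with 1 gene symbol; each point is 1 array, coloured by group, with the NSC arrays marked by mouse line. PC1 (66.7% of variance) parts tumour from NSC arrays, and on PC2 (8.65%) the mGC2_NES arrays lie at 18.2 to 23.3, mGC3_CNP at -6.63 to 0.03 and mGC1_GFAP at -24.98 to -14.4.

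The comparison of tumour with NSC cultures asked what distinguishes the glioblastoma cells from non-tumour cells grown alike. Tumour cultures carried high levels of genes of the oligodendrocyte precursor lineage and low levels of several astrocyte and stem cell genes that were high in NSC cultures. The neuregulin receptor Erbb3 rose by at least 5.81 ± 0.09 (limma adjusted p = 3.18e-12), from 6.57 ± 0.13 in NSC (SD, n = 3) to 12.38 ± 0.27 in tumour cultures (SD, n = 9). The PDGF receptor Pdgfra rose by 3.80 ± 0.06 to 13.38 ± 0.05 (SD, n = 9). The epidermal growth factor receptor Egfr changed by -5.43 ± 0.11, also a lower bound on the size, from 11.76 ± 0.34 in NSC (SD, n = 3) to 6.34 ± 0.05 in tumour cultures (SD, n = 9).

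In all, 8004 of 21780 probe sets were called (36.7%, 7442 genes), 3825 higher and 4179 lower in tumour cultures, and 9545 had an unadjusted p under 0.05. At least 2-fold differences were seen for 835 higher and 769 lower probe sets. Besides Erbb3, the genes named for large rises were Capn6 (5.57 ± 0.14), the matrix genes Hapln1 (5.54 ± 0.49) and Acan (4.78 ± 0.13), the semaphorin Sema3d (5.24 ± 0.29), the glutamate receptor subunit Gria4 (5.16 ± 0.14), the transcription factor gene Foxf1 (5.02 ± 0.16), the carbonic anhydrase Car6 (5.00 ± 0.17), Fry (4.63 ± 0.15) and S100b (4.62 ± 0.12). Those named for large falls were Fndc3c1 (-6.83 ± 0.10), the interferon-induced membrane protein gene Ifitm3 (-6.48 ± 0.19), the laminin receptor subunit Itga6 (-5.69 ± 0.13), the folate enzyme Aldh1l1 (-5.67 ± 0.08), Crip2 (-5.44 ± 0.23), Egfr, the gap junction gene Gja1 (-5.31 ± 0.06), Anxa5 (-5.20 ± 0.57), Lxn (-5.00 ± 0.43) and S100a11 (-4.93 ± 0.27). Of these 20 genes only S100a11 had its lower mean above 7.42, the highest reading of a transcript taken as absent. The differences of all the others, Erbb3 and Egfr among them, are lower bounds with no order. These 20 genes kept an adjusted p under 0.05 without each of the 12 arrays in turn. Among called probe sets, 323 belonged to predicted genes, and 4 genes, Exosc3, Fut11, Ndfip2 and Rbbp6, picked out after their values were seen, had probe sets called in both directions.

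Glial lineage lists went in opposite directions. Of the oligodendrocyte precursor list, 12 of 15 measured members rose, 0 fell and 3 did not pass the test, against 13 and 1 adjusted over the list alone. Its leading members were the transcription factor gene Sox10 (4.51 ± 0.05), Pdgfra, C1ql1 (4.14 ± 0.15) and the proteoglycan gene Cspg4 (2.66 ± 0.11), and the list passed camera (adjusted p = 1.20e-10, and adjusted p = 0.0453 with an estimated correlation). Of the differentiated oligodendrocyte list, 9 of 17 measured members rose, 2 fell and 6 did not pass the test, against 10 and 3 adjusted over the list alone. It rose as a list, led by Bcas1 (3.82 ± 0.11), Ugt8a (2.49 ± 0.08), Gal3st1 (2.56 ± 0.09) and Myrf (2.54 ± 0.19). Camera gave it adjusted p = 0.00391, and adjusted p = 0.357 with an estimated correlation. Of the astrocyte list, 3 of 16 measured members rose, 9 fell and 4 did not pass the test, against 3 and 9 adjusted over the list alone. Gja1, Aldh1l1 and the water channel gene Aqp4 (-2.38 ± 0.08) fell while S100b, also made by oligodendrocyte lineage cells, rose. Camera gave the astrocyte list adjusted p = 0.00391, and adjusted p = 0.122 with an estimated correlation. Of the neural stem cell list, 0 of 14 measured members rose, 10 fell and 4 did not pass the test, against 0 and 12 adjusted over the list alone. Egfr, Nes, Prom1 (-1.65 ± 0.10) and Nr2e1 (-1.76 ± 0.10) fell. Camera gave the neural stem cell list adjusted p = 2.02e-07, and adjusted p = 0.0548 with an estimated correlation.

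The glioblastoma subtype lists also parted. Of the proneural list, 7 of 14 measured members rose, 3 fell and 4 did not pass the test, against 8 and 4 adjusted over the list alone. Nkx2-2 (2.33 ± 0.16) led it beside Sox10, Erbb3 and Pdgfra. Dll3, Olig2, Nkx2-2, Pdgfra and Sox10 also belong to the oligodendrocyte precursor list, so the proneural rise is not a separate result from the rise of that list. Camera gave the proneural glioblastoma list adjusted p = 0.00391, and adjusted p = 0.221 with an estimated correlation. Of the mesenchymal list, 3 of 23 measured members rose, 12 fell and 8 did not pass the test, against 3 and 13 adjusted over the list alone. Itga5 (-2.47 ± 0.09), Timp1 (-3.56 ± 0.24) and the hyaluronan receptor gene Cd44 fell, and Chil1 rose by 3.02 ± 0.13. Camera gave the mesenchymal glioblastoma list adjusted p = 8.50e-04, and adjusted p = 0.248 with an estimated correlation.

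Positional identity genes also differed. Of the forebrain patterning list, 0 of 11 measured members rose, 9 fell and 2 did not pass the test, against 0 and 9 adjusted over the list alone. Gsx2 (-1.70 ± 0.07), Otx1 (-1.44 ± 0.09), Lhx2 (-1.04 ± 0.09) and Otx2 (-0.88 ± 0.08) led it. Camera gave it adjusted p = 1.23e-05, and adjusted p = 0.0611 with an estimated correlation. Of the Hox list, 5 of 25 measured members rose, 0 fell and 20 did not pass the test, against 5 and 0 adjusted over the list alone. Hoxa5 (2.66 ± 0.10), Hoxa3 (1.45 ± 0.08), Hoxa4 (1.01 ± 0.11) and Hoxa2 (0.51 ± 0.05) led those that rose, and the list median was 0.07. Camera gave the Hox genes list adjusted p = 0.0488, and adjusted p = 0.361 with an estimated correlation.

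Of the DNA replication list, 0 of 20 measured members rose, 19 fell and 1 did not pass the test, against 0 and 20 adjusted over the list alone. Rrm2 (-1.18 ± 0.10), Gins2 (-0.84 ± 0.08), E2f1 (-0.69 ± 0.07) and Mcm4 (-0.55 ± 0.06) led it. Camera gave the DNA replication list adjusted p = 2.03e-09, and adjusted p = 0.221 with an estimated correlation. The mitosis list did not pass (adjusted p = 0.509), and 0 of 20 measured members rose, 2 fell and 18 did not pass the test, against 0 and 1 adjusted over the list alone. Of the drug transport and detoxification list, 1 of 18 measured members rose, 13 fell and 4 did not pass the test, against 1 and 13 adjusted over the list alone. Gstm1 (-4.10 ± 0.20), Nqo1 (-2.21 ± 0.12), Gclm (-0.88 ± 0.08) and the cystine transporter gene Slc7a11 (-3.22 ± 0.30) fell, and the list passed (adjusted p = 6.80e-05, and adjusted p = 0.0453 with an estimated correlation). Of the p53 target list, 1 of 16 measured members rose, 9 fell and 6 did not pass the test, against 1 and 9 adjusted over the list alone. The death receptor genes Tnfrsf10b (-2.04 ± 0.20) and Fas (-1.17 ± 0.16) and Btg2 (-1.33 ± 0.18) fell, and Rrm2b (0.46 ± 0.07) rose. Camera gave the p53 targets list adjusted p = 0.00391, and adjusted p = 0.416 with an estimated correlation. Of the Notch list, 3 of 14 measured members rose, 10 fell and 1 did not pass the test, against 3 and 10 adjusted over the list alone. Lfng (-4.78 ± 0.10), Notch2 (-1.74 ± 0.18) and Mfng (-1.66 ± 0.13) fell, and the ligand gene Jag1 (1.45 ± 0.12) rose. Camera gave the Notch pathway list adjusted p = 0.00391, and adjusted p = 0.357 with an estimated correlation. Of the extracellular matrix list, 3 of 22 measured members rose, 11 fell and 8 did not pass the test, against 3 and 11 adjusted over the list alone. Lamb1 (-2.69 ± 0.12), Fn1 (-2.36 ± 0.27) and Lamc1 (-0.92 ± 0.13) fell, and Lama4 (3.02 ± 0.14) rose. Camera gave the extracellular matrix list adjusted p = 0.0472, and adjusted p = 0.507 with an estimated correlation.

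**Figure D2:**
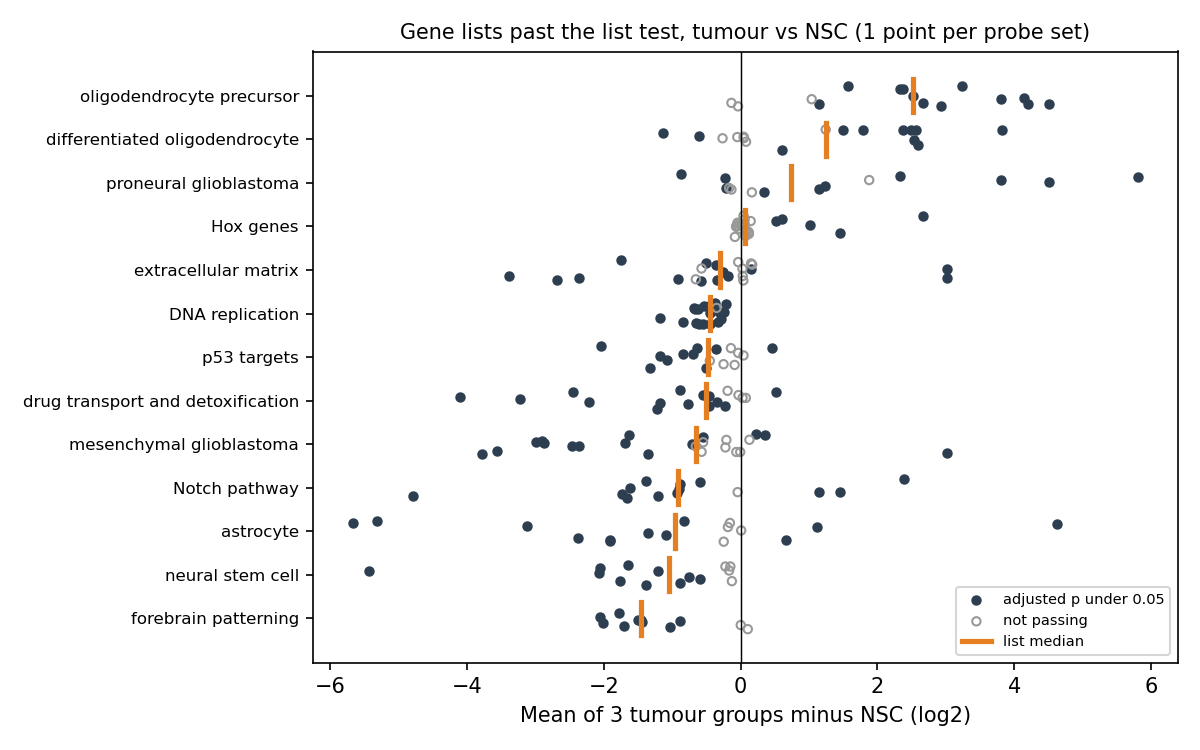
Difference between the mean of the 3 tumour groups and the NSC mean (log2, horizontal axis) for each measured gene, by its probe set with the smallest p, of the 13 lists that passed the list test (vertical axis); filled points have an adjusted p under 0.05, open points do not, and bars mark list medians of these points. The oligodendrocyte precursor list has a median of 2.53 and the forebrain patterning list one of -1.46.

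Markers of cell types other than glia and stem cells were measured to describe the cultures, and none of these 4 lists passed the list test. In the microglia and macrophage list 1 of 14 rose and 2 fell, against 0 and 2 adjusted over the list alone. In the endothelial list 1 of 10 rose and 1 fell, against 1 and 1 adjusted over the list alone. In the pericyte and fibroblast list 2 of 10 rose and 2 fell, against 2 and 2 adjusted over the list alone. In the neuroblast and neuron list 3 of 20 rose and 7 fell, against 4 and 8 adjusted over the list alone. The smooth muscle actin gene Acta2 (-2.76 ± 0.29) and the interneuron lineage genes Dlx1 (-1.46 ± 0.14) and Dlx2 (-1.77 ± 0.17) fell, as did P2ry12 (-0.81 ± 0.14) and Cd68 (-0.57 ± 0.11) of the microglia list. For the microglia and the pericyte lists the median lay above 0 and the mean and the test below it. The list adjusted p-values were 0.988, 0.847, 0.847 and 0.392.

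Of the other fixed genes, Nes changed by -2.07 ± 0.15 and Gfap by -1.35 ± 0.17, both lower in tumour cultures. Pdgfb rose by 0.99 ± 0.10, Cnp by 0.61 ± 0.15 (adjusted p = 0.00782) and Cdkn2a by 0.69 ± 0.17 (adjusted p = 0.00793), and Cdkn2b changed by -1.09 ± 0.28 (adjusted p = 0.00889). PDGFB was encoded by the virus, and the mice with tumours lacked Arf, encoded at Cdkn2a. What the probe sets of Pdgfb and Cdkn2a read in these cultures was not checked. Pdgfb also lies on chromosome 15, whose genes lay higher in the tumour arrays. The arrays of both sides overlapped for Cnp and Cdkn2b. Without the N/tv-a NSC culture Cdkn2b no longer passed, at -0.92. Among list members and fixed genes named above for this comparison, the differences of Aqp4, Prom1, Itga5, Timp1, Chil1, Gsx2, Otx2, Hoxa2, Hoxa3, Hoxa5, Nqo1, Slc7a11, Tnfrsf10b, Fas, Lfng, Lamb1, Acta2, Dlx1, P2ry12 and Gfap are lower bounds by the same reading. For Otx2, Hoxa2, Fas and P2ry12 the tumour and the NSC mean both lay below 7.42, so presence of these transcripts on either side was not shown.

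The 3 tumour groups differed in 882 probe sets by the moderated F test in limma (827 genes, 4.05% of 21780), and 4242 had an unadjusted p under 0.05. The count was 222, 521 or 305 without mGC1_GFAP replicate 1, 2 or 3, 299 or 293 without mGC2_NES replicate 2 or 3, and 532 or 486 without mGC3_CNP replicate 2 or 3.

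The comparison of mGC1_GFAP with mGC3_CNP set tumours of the astrocyte promoter line against those of the oligodendrocyte lineage promoter line. The calls were single genes, and a difference in the glial lineage lists fixed for these cells was neither shown nor excluded. The natural killer receptor ligand H60b was higher in mGC1_GFAP by at least 3.35 ± 0.40 (limma adjusted p = 0.0135), at 8.89 ± 0.50 against 5.54 ± 0.61 (SD, n = 3 each). The lysophospholipase gene Gdpd3 differed by -3.56 ± 0.30, a lower bound as well (adjusted p = 0.00344), at 6.36 ± 0.13 in mGC1_GFAP and 9.92 ± 0.37 in mGC3_CNP, and the secreted Wnt antagonist Sfrp1 by -2.56 ± 0.34 (adjusted p = 0.0205).

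Of 21780 probe sets, 106 were called (98 genes), 60 higher and 46 lower in mGC1_GFAP, and 2816 had an unadjusted p under 0.05. At least 2-fold differences were seen for 15 higher and 14 lower. The other genes named by the rule as higher in mGC1_GFAP were Olfml3 (1.85 ± 0.23), the nuclear receptor gene Nr4a2 (1.83 ± 0.26), the ribosomal protein gene Rps21 (1.26 ± 0.10), Tnks1bp1 (1.21 ± 0.10), Fam135b (1.19 ± 0.19), Phxr4 (1.16 ± 0.14), Zfp971 (1.14 ± 0.11), Stk10 (1.11 ± 0.14) and the R-spondin receptor Lgr5 (1.10 ± 0.13). Lower in mGC1_GFAP were also Npl (-2.18 ± 0.23), Rerg (-2.02 ± 0.19), Gpx8 (-1.77 ± 0.25), Cpeb1 (-1.60 ± 0.25), the small heat shock protein gene Cryab (-1.46 ± 0.21), Tmbim1 (-1.20 ± 0.19), Chil1 (-1.20 ± 0.17) and Usp44 (-1.15 ± 0.13). The differences of Fam135b, Phxr4, Rerg, Cpeb1 and Usp44 are lower bounds. Usp44 had means of 6.12 in mGC1_GFAP and 7.27 in mGC3_CNP, both below 7.42, so its presence in either group was not shown. Predicted genes made up 6 of the calls. Arrays of both groups did not overlap for any of the 106 calls, nor for 19.4% of all probe sets, against 10% that chance gives.

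None of the promoter genes differed at the threshold between these groups. Gfap differed by -0.06 ± 0.13 (adjusted p = 0.903), Nes by 0.40 ± 0.19 (0.424) and Cnp by 0.07 ± 0.20 (0.926). Mean Gfap values were 6.49 in mGC1_GFAP, 6.58 in mGC2_NES and 6.55 in mGC3_CNP, all below 7.42. For Gfap, the comparisons of tumour groups thus cannot tell equal levels from absence. Pdgfra (-0.05 ± 0.06), Pdgfb (-0.11 ± 0.10), Cdkn2a (-0.14 ± 0.23) and Cdkn2b (-0.65 ± 0.36) did not pass either. In the astrocyte list 0 of 16 were higher and 0 were lower (by limma, with 1 and 1 at an unadjusted p under 0.05), against 0 and 0 adjusted over the list alone. In the oligodendrocyte precursor list 0 of 15 were higher and 0 were lower (by limma, with 0 and 3 at an unadjusted p under 0.05), against 0 and 0 adjusted over the list alone. In the differentiated oligodendrocyte list 0 of 17 were higher and 0 were lower (by limma, with 0 and 0 at an unadjusted p under 0.05), against 0 and 0 adjusted over the list alone. Single members of other lists were called, namely Chil1 of the mesenchymal list, Lgr5 of the Wnt targets, Tgfb2 (-1.03 ± 0.17) of the TGF-beta list and Srxn1 (-0.34 ± 0.06) of the detoxification list.

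Of the DNA replication list, 0 of 20 measured members were higher, 0 were lower and 20 did not pass the test (by limma, with 11 and 0 at an unadjusted p under 0.05), against 9 and 0 adjusted over the list alone. It was higher in mGC1_GFAP as a list (adjusted p = 8.12e-08, and adjusted p = 0.944 with an estimated correlation), and Mcm5 (0.27 ± 0.07), Mcm4 (0.29 ± 0.08), Cdt1 (0.36 ± 0.10) and Gins2 (0.34 ± 0.10) were its leading members. In the hypoxia list 0 of 20 were higher and 0 were lower (by limma, with 0 and 1 at an unadjusted p under 0.05), against 0 and 0 adjusted over the list alone. It was lower as a list (adjusted p = 0.0235, and adjusted p = 0.944 with an estimated correlation). Kdm3a stood at -0.29 ± 0.12, P4ha1 at -0.26 ± 0.13, Vegfa at -0.51 ± 0.28 and Bnip3 at -0.91 ± 0.51. In the cholesterol synthesis list 0 of 16 were higher and 0 were lower (by limma, with 5 and 2 at an unadjusted p under 0.05), against 1 and 1 adjusted over the list alone. Camera gave it a higher level in mGC1_GFAP (adjusted p = 0.0177, and adjusted p = 0.944 with an estimated correlation). Its leading members had both signs, with Insig1 at -0.41 ± 0.09, Dhcr7 at -0.36 ± 0.12, Nsdhl at 0.36 ± 0.09 and Msmo1 at 0.29 ± 0.09. No other list passed.

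The count of 106 moved with the arrays and the model. It was 30, 52 or 38 without mGC1_GFAP replicate 1, 2 or 3, 49 or 46 without mGC2_NES replicate 2 or 3, and 65, 44 or 24 without mGC3_CNP replicate 1, 2 or 3, and 28 with Y-linked transcripts, present in 0 of 3 mGC3_CNP cultures, as a covariate. The balance of 60 higher and 46 lower turned to 12 and 18 without mGC1_GFAP replicate 1, to 11 and 13 without mGC3_CNP replicate 3 and to 10 and 18 with that covariate. Of the 20 genes named by the rule, 6 (Rps21, Tnks1bp1, Zfp971, Gdpd3, Npl and Rerg) passed without each of the 9 arrays in turn and 14 did not. H60b, Lgr5, Phxr4 and Usp44 lost their calls without mGC1_GFAP replicate 1 or mGC3_CNP replicate 3, Olfml3 without either of these or mGC1_GFAP replicate 3, Stk10 without mGC3_CNP replicate 3, and Sfrp1 without mGC1_GFAP replicate 3 or mGC3_CNP replicate 2. Nr4a2 and Chil1 passed without only 4 of the 9 arrays, Cryab and Gpx8 without only 3, and Fam135b and Cpeb1 only without mGC1_GFAP replicate 3. Tmbim1 lost its call whichever of the 9 arrays was left out, and Fam135b did not pass as the mean of its 5 probe sets.

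The comparison of mGC1_GFAP with mGC2_NES gave the largest number of calls between tumour groups. Among cell cycle genes, 17 of 20 members of the DNA replication list and 9 of 20 of the mitosis list were higher in mGC1_GFAP, and neither list passed with an estimated correlation (adjusted p = 0.462 for both). The ubiquitin ligase gene Trim13 was higher by at least 4.94 ± 0.17 (limma adjusted p = 4.29e-06), at 9.80 ± 0.26 against 4.86 ± 0.22 (SD, n = 3 each), and AA388235 differed by -4.12 ± 0.17, a lower bound as well (adjusted p = 1.01e-05). Nes, the gene whose promoter defines the N/tv-a line, was higher in mGC1_GFAP by 1.01 ± 0.19 (adjusted p = 0.0181).

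Of 21780 probe sets, 1336 were called (1242 genes), 679 higher and 657 lower in mGC1_GFAP (874 and 526 with each array centred on its median), and 4479 had an unadjusted p under 0.05. At least 2-fold differences were seen for 57 higher and 86 lower. H60b (2.91 ± 0.40), Zfp991 (2.59 ± 0.46), Tmem47 (2.45 ± 0.47) and Epb41l3 (2.29 ± 0.14) were also higher, and the adenylate cyclase gene Adcy2 (-4.19 ± 0.35), Gdpd3 (-3.66 ± 0.30), the proenkephalin gene Penk (-3.55 ± 0.48) and Tmem100 (-3.41 ± 0.63) were lower. All of these but Epb41l3 and Tmem100 are lower bounds. Predicted genes made up 39 of the calls. Arrays of both groups did not overlap for any of the 1336 calls, nor for 26.5% of all probe sets, against 10% that chance gives. Gfap (-0.08 ± 0.13), Cnp (0.36 ± 0.20), Pdgfra (-0.01 ± 0.06), Pdgfb (-0.16 ± 0.10), Cdkn2a (-0.55 ± 0.23) and Cdkn2b (0.51 ± 0.36) did not pass.

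Of the DNA replication list, 17 of 20 measured members were higher, 0 were lower and 3 did not pass the test, against 19 and 0 adjusted over the list alone. Pola1 (0.80 ± 0.08), Cdt1 (0.90 ± 0.10), Mcm5 (0.62 ± 0.07) and Mcm4 (0.66 ± 0.08) led it. Camera gave the DNA replication list adjusted p = 6.16e-21, and adjusted p = 0.462 with an estimated correlation. Of the mitosis list, 9 of 20 measured members were higher, 0 were lower and 11 did not pass the test, against 19 and 0 adjusted over the list alone. Birc5 (0.71 ± 0.12), Bub1 (0.60 ± 0.11), Ccna2 (0.37 ± 0.07) and Ube2c (0.34 ± 0.07) led it. Camera gave the mitosis list adjusted p = 8.11e-14, and adjusted p = 0.462 with an estimated correlation. Relative to the mean over 12 arrays, the DNA replication list stood at 0.13 ± 0.04 in mGC1_GFAP, -0.43 ± 0.12 in mGC2_NES, -0.08 ± 0.10 in mGC3_CNP and 0.38 ± 0.03 in NSC (SD, n = 3 each). The mitosis list stood at 0.16 ± 0.02, -0.28 ± 0.20, 0.07 ± 0.11 and 0.05 ± 0.14. No other list passed. In the neural stem cell list 2 of 14 were higher and 0 were lower, against 2 and 0 adjusted over the list alone, and its higher members were Nr2e1 (0.68 ± 0.12) and Nes. In the neuroblast and neuron list 2 of 20 were higher and 0 were lower, against 2 and 1 adjusted over the list alone. In the mesenchymal glioblastoma list 0 of 23 were higher and 2 were lower, against 0 and 3 adjusted over the list alone, and in the Notch list 0 of 14 were higher and 2 were lower, against 0 and 2 adjusted over the list alone. In the TGF-beta and BMP list 1 of 13 were higher and 2 were lower, against 1 and 3 adjusted over the list alone. In the cholesterol synthesis list 0 of 16 were higher and 2 were lower, against 1 and 2 adjusted over the list alone, and in the stress and immediate early list 0 of 12 were higher and 2 were lower, against 2 and 2 adjusted over the list alone. The other lists held at most 1 call in each direction.

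**Figure D3:**
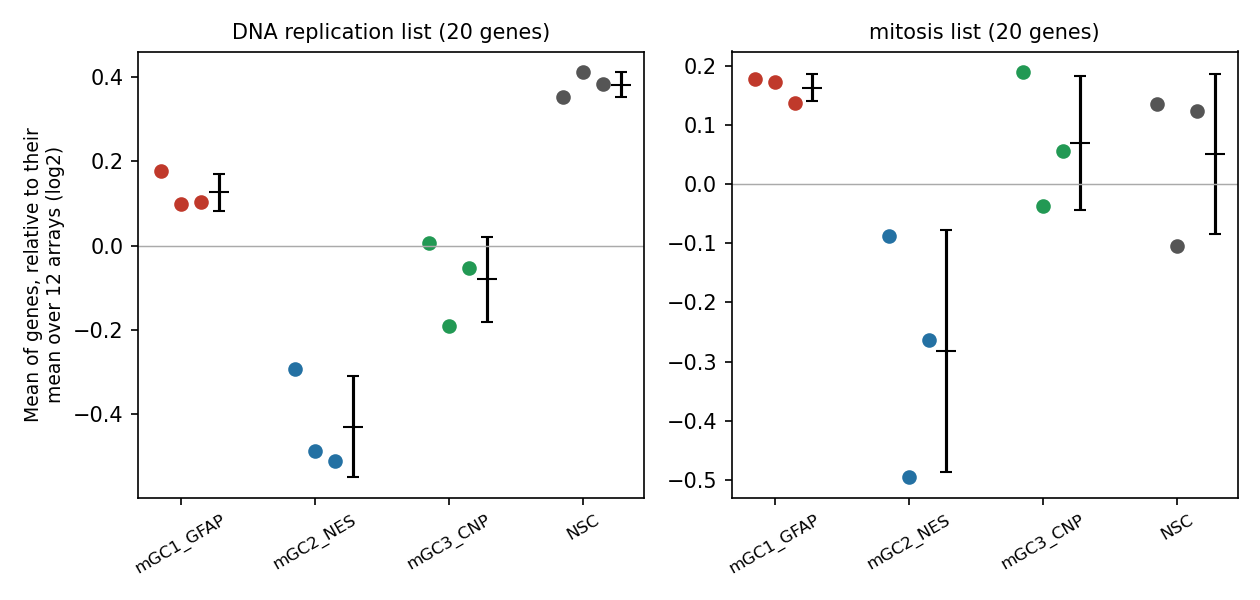
Mean of the measured genes of the DNA replication list and of the mitosis list in each array, relative to their mean over the 12 arrays (log2); points are arrays, bars are mean ± SD (n = 3). Both lists are lowest in mGC2_NES, at -0.43 and -0.28 on average.

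The count of 1336 was 534 or 629 without mGC1_GFAP replicate 1 or 3 and 622 or 693 without mGC2_NES replicate 2 or 3. The balance of 679 higher and 657 lower turned to 255 and 279 without mGC1_GFAP replicate 1 and to 284 and 338 without mGC2_NES replicate 2. The members of the mitosis list that passed numbered 2, 4 or 3 without mGC1_GFAP replicate 1, 2 or 3 and 15, 3 or 4 without mGC2_NES replicate 1, 2 or 3. Those of the DNA replication list numbered 9 without mGC1_GFAP replicate 1 and 9 or 11 without mGC2_NES replicate 2 or 3. Of the 10 genes named by the rule, 7 passed without each of the 9 arrays, and Tmem47, Zfp991 and Tmem100 did not. Tmem47 lost its call without mGC1_GFAP replicate 2 or 3 or mGC2_NES replicate 1 or 2, Zfp991 without mGC1_GFAP replicate 1 or mGC2_NES replicate 2, Tmem100 without any 1 mGC2_NES array, and Nes without mGC2_NES replicate 2 or 3. Bub1 lost its call without mGC1_GFAP replicate 1, Ccna2 without that array or mGC2_NES replicate 2 or 3, and Ube2c without mGC1_GFAP replicate 2 or 3 or mGC2_NES replicate 2.

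The comparison of mGC2_NES with mGC3_CNP set tumours of the progenitor promoter line against those of the oligodendrocyte lineage promoter line. AA388235 was higher in mGC2_NES by 4.27 ± 0.17 (limma adjusted p = 1.09e-05), as were Adcy2 (3.80 ± 0.35), the cartilage matrix gene Cnmd (2.25 ± 0.19), Efhd1 (2.04 ± 0.34) and the guanylate cyclase gene Gucy2f (1.99 ± 0.09). Trim13 was lower (-4.75 ± 0.17, adjusted p = 6.16e-06), as were the synaptic vesicle gene Sv2c (-2.25 ± 0.29), Epb41l3 (-2.06 ± 0.14), Rerg (-2.04 ± 0.19) and Cryab (-1.94 ± 0.21). The differences of AA388235, Adcy2, Gucy2f, Trim13 and Rerg are lower bounds.

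Of 21780 probe sets, 100 were called (98 genes), 58 higher and 42 lower in mGC2_NES, and 2900 had an unadjusted p under 0.05. At least 2-fold differences were seen for 18 higher and 20 lower. Predicted genes made up 3 of the calls. Arrays of both groups did not overlap for any of the 100 calls, nor for 18.2% of all probe sets, against 10% that chance gives. None of the fixed genes passed, with Nes at -0.61 ± 0.19 (adjusted p = 0.213), Cdkn2b at -1.16 ± 0.36 (0.212), Cdkn2a at 0.41 ± 0.23, Cnp at -0.29 ± 0.20, Gfap at 0.02 ± 0.13, Pdgfb at 0.06 ± 0.10 and Pdgfra at -0.04 ± 0.06.

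Of the DNA replication list, 0 of 20 measured members were higher, 1 was lower and 19 did not pass the test, against 0 and 17 adjusted over the list alone. The polymerase gene Pola1 was lower (-0.58 ± 0.08), and Cdt1 (-0.54 ± 0.10), Mcm5 (-0.35 ± 0.07) and Mcm3 (-0.44 ± 0.09) did not pass over all genes. Camera gave the DNA replication list adjusted p = 1.06e-16, and adjusted p = 0.366 with an estimated correlation. In the mitosis list 0 of 20 were higher and 0 were lower (by limma, with 0 and 15 at an unadjusted p under 0.05), against 0 and 15 adjusted over the list alone. Its leading members were Ttk at -0.46 ± 0.11, Tpx2 at -0.46 ± 0.11, Nusap1 at -0.32 ± 0.08 and Ccna2 at -0.27 ± 0.07. Camera gave the mitosis list adjusted p = 2.75e-13, and adjusted p = 0.473 with an estimated correlation. In the interferon response list 0 of 21 were higher and 0 were lower (by limma, with 7 and 1 at an unadjusted p under 0.05), against 5 and 0 adjusted over the list alone. As a list it was higher in mGC2_NES (adjusted p = 0.00174, and adjusted p = 0.175 with an estimated correlation). The antiviral gene Mx2 stood at 1.19 ± 0.23, Rtp4 at 0.51 ± 0.13, Ifit3 at 0.48 ± 0.12 and Stat2 at 0.33 ± 0.09. In the neural stem cell list 0 of 14 were higher and 0 were lower (by limma, with 0 and 3 at an unadjusted p under 0.05), against 0 and 1 adjusted over the list alone. It was lower as a list (adjusted p = 0.0454, and adjusted p = 0.473 with an estimated correlation), with Nr2e1 at -0.49 ± 0.12, Sox2 at -0.27 ± 0.12 and Hes1 at -0.74 ± 0.36. In the hypoxia list 0 of 20 were higher and 0 were lower (by limma, with 0 and 1 at an unadjusted p under 0.05), against 0 and 0 adjusted over the list alone. It was lower as a list (adjusted p = 0.0454, and adjusted p = 0.759 with an estimated correlation), with P4ha1 at -0.31 ± 0.13, Pdk1 at -1.01 ± 0.56, Ldha at -0.32 ± 0.20 and Egln3 at -0.56 ± 0.36. In the cholesterol synthesis list 0 of 16 were higher and 0 were lower (by limma, with 5 and 0 at an unadjusted p under 0.05), against 0 and 0 adjusted over the list alone. It was higher as a list (adjusted p = 0.0454, and adjusted p = 0.75 with an estimated correlation), with Msmo1 at 0.28 ± 0.09, Hmgcs1 at 0.40 ± 0.13, Sc5d at 0.23 ± 0.08 and Mvd at 0.27 ± 0.10. Tgfb2 (1.14 ± 0.17) of the TGF-beta list was called on its own.

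The balance of 58 higher and 42 lower turned to 48 and 51 with each array centred on its median, to 53 and 80 without mGC2_NES replicate 1, to 29 and 31 without mGC2_NES replicate 3, to 31 and 33 without mGC3_CNP replicate 2 and to 17 and 23 with the Y-linked covariate. The count of 100 was 61 or 60 without mGC2_NES replicate 2 or 3, 64 or 42 without mGC3_CNP replicate 2 or 3, and 40 with Y-linked transcripts, present in 0 of 3 mGC3_CNP cultures, as a covariate. Of the 10 genes named by the rule, 8 passed without each of the 9 arrays. Sv2c lost its call without mGC2_NES replicate 3 or mGC3_CNP replicate 2 or 3, Pola1 without mGC2_NES replicate 2 or 3 or mGC3_CNP replicate 3, and Efhd1 passed only without mGC1_GFAP replicate 1 or 3.

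**Figure D4:**
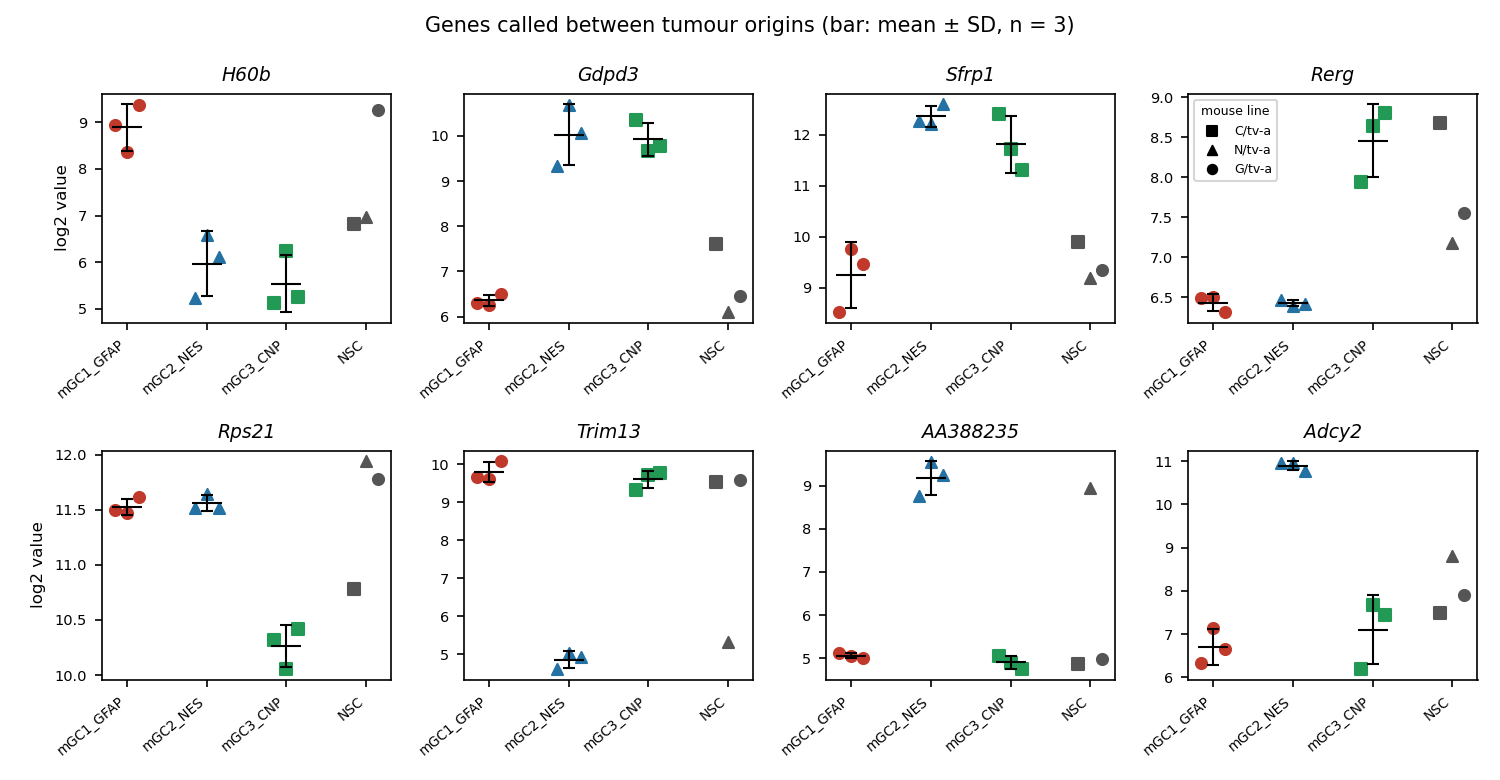
Deposited log2 values (vertical axis) of 8 genes called between tumour groups, by group (horizontal axis); points are arrays, shaped by mouse line, and bars are mean ± SD for the tumour groups (n = 3). For Trim13 and AA388235 the NSC culture of the N/tv-a line stands apart from the other NSC cultures on the same side as the mGC2_NES arrays.

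The NSC cultures of the 3 lines were used to see whether differences between tumour groups were also present between lines without a tumour. The C/tv-a NSC culture had no Y-linked transcripts (mean 5.15), like the mGC3_CNP cultures, while the G/tv-a (8.39) and N/tv-a (9.28) NSC cultures had them. In the comparisons with mGC3_CNP, line and sex of the NSC cultures thus cannot be told apart. The G/tv-a NSC culture also had Xist, at 11.9, against 5.67 in the N/tv-a NSC culture. Between these cultures too, a difference of line cannot be told from one of sex. Of the 106 probe sets called between mGC1_GFAP and mGC3_CNP, 84 had the same sign between the G/tv-a and C/tv-a NSC cultures (79.2%, exact 95% interval 70.3 to 86.5%), with a median NSC difference, turned to the tumour sign, of 0.33 against 0.77 in tumours. Of 1336 called between mGC1_GFAP and mGC2_NES, 854 had the same sign (63.9%, 61.3 to 66.5%; median 0.07 against 0.52), and of 100 between mGC2_NES and mGC3_CNP, 76 (76.0%, 66.4 to 84.0%; median 0.28 against 0.84). Each median lay at the 100th percentile of 10000 random lists, whose middle 95% ran from -0.04 to 0.05 in the first comparison. The intervals and the random lists treat probe sets as independent, which they are not. The random lists were also not matched on the spread of the probe sets. A departure of 1 NSC culture could thus also place the medians at that percentile, which cannot decide about the line. With the NSC difference of each probe set subtracted, which carries no test with 1 NSC culture per line, the medians were 0.46, 0.42 and 0.50. Trim13 differed by 4.28 between the G/tv-a and N/tv-a NSC cultures and AA388235 by -3.95, and H60b differed by 2.44 between the G/tv-a and C/tv-a cultures, all 3 lower bounds. Rps21 differed by 1.00 between the G/tv-a and C/tv-a cultures. Zfp971 (1.22) and Lgr5 (1.48) differed by more between these NSC cultures than between the tumour groups. Cryab (0.0033) and Nr4a2 (0.07) did not differ in this way, and Fam135b (-0.93) had the opposite sign.

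Medians over the expressed genes of each chromosome, examined after the values were seen, differed between tumour and NSC cultures for chromosome 15. Genes counted as expressed where their mean over the arrays exceeded the mean array median, and shifts were taken relative to the NSC mean and to the median over autosomes. The 431 genes of chromosome 15 lay higher in 9 of 9 tumour arrays, by 0.29 ± 0.05 on the log2 scale (mean ± SD of 9 arrays, range 0.17 to 0.33), and 78.0% of them were higher, against 48.8% on the other autosomes. The tumour mean of every other chromosome lay between -0.08 and 0.05. Single tumour arrays were beyond 0.1 for chromosome 14 in mGC3_CNP replicate 1 (-0.35), for chromosomes 6 (0.20), 11 (0.13), 14 (-0.11) and 17 (0.18) in mGC1_GFAP replicate 1, for chromosome 11 in mGC1_GFAP replicate 3 (0.14), for chromosome 14 in mGC2_NES replicate 1 (-0.12) and for chromosome 7 in mGC3_CNP replicate 1 (0.16).

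**Figure D5:**
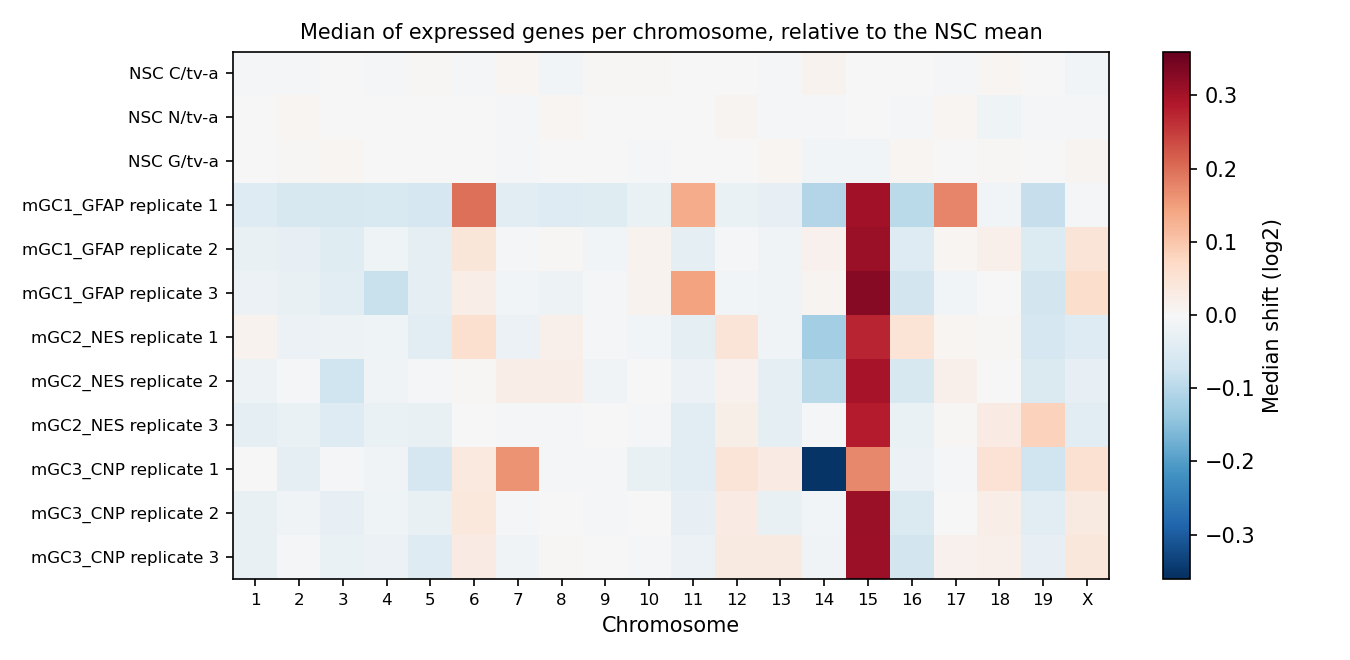
Median over the expressed genes of each chromosome (columns) in each of the 12 arrays (lines of the map), relative to the mean of the NSC arrays and to the autosomal median of the array (log2, colour scale from blue for lower to red for higher). Chromosome 15 is higher in the 9 tumour arrays, by 0.17 to 0.33.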

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

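The comparison of named genes with the NSC culture of each line was chosen only after the results were seen.

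In 4 named genes, all 3 tumour cultures of 1 line lay above the NSC culture of that line and all 3 of another line lay below theirs. The difference between lines was not tested, because each line had 1 NSC culture, and a departure of that culture alone would look the same. Most named genes were chosen for large differences between groups, which favours such positions. How often they occur over all probe sets was not counted. For Fam135b in each line and Adcy2 in mGC1_GFAP the lower level lay below 7.42, so these differences are lower bounds. Fam135b stood at 1.01 above the NSC culture in mGC1_GFAP, at -1.56 in mGC2_NES and at -1.11 in mGC3_CNP (mean log2 differences). Nr4a2 stood at 1.21 in mGC1_GFAP, 0.65 in mGC2_NES and -0.55 in mGC3_CNP, and Adcy2 at 2.09 in mGC2_NES and -1.20 in mGC1_GFAP. Sv2c stood at 1.20 in mGC3_CNP and -0.54 in mGC2_NES.

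Probe sets without a single gene symbol take no part in the main comparisons between groups. Of 6490 such probe sets, limma called 516 higher and 817 lower in tumour than in NSC cultures (20.5%, against 36.1% of the probe sets with 1 symbol when all were adjusted together).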

How the results depend on the processing

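The covariate for Y-linked transcripts, the removal of X- and Y-linked genes and the leave-one-out counts of list members were tests chosen only after the results were seen. The tumour against NSC count of 8004 stayed within 1.5 times under each alternative, from 6777 to 9196, and the F test count of 882 did so except when single arrays were left out (222 to 945). Without 1 array, the counts ran from 24 to 106 for mGC1_GFAP against mGC3_CNP, from 534 to 1619 for mGC1_GFAP against mGC2_NES, from 42 to 133 for mGC2_NES against mGC3_CNP and from 6777 to 8114 for tumour against NSC, and the higher members in mGC1_GFAP against mGC2_NES from 9 to 19 for DNA replication and from 2 to 15 for mitosis. For mGC1_GFAP against mGC3_CNP the 106 calls became 195 with array weights (all 106 among them), 165 over all probe sets of the table, 65 with all 12 arrays in the fit, 27 with only the 6 arrays of both groups and 28 with the Y-linked covariate. For mGC2_NES against mGC3_CNP the 100 calls became 164 over all probe sets, 62 with the 6 arrays and 40 with the covariate. With the 6 arrays, 13 higher and 14 lower were called for mGC1_GFAP against mGC3_CNP and 532 and 544 for mGC1_GFAP against mGC2_NES, which gave 583 and 607 with 1 value per gene. The fits on 6 arrays or without 1 array hold fewer arrays, and the cause of the other changes was not tested. With an estimated correlation, 0, 0, 0 and 2 lists passed where 3, 2, 6 and 13 did in mGC1_GFAP against mGC3_CNP, mGC1_GFAP against mGC2_NES, mGC2_NES against mGC3_CNP and tumour against NSC. Fry, which does not compare a list with other genes, gave 0, 5, 2 and 18 in the same comparisons, and camera on 1 value per gene gave 5, 2, 4 and 12. It added the ERK pathway output (adjusted p = 0.0429) and antigen presentation (0.0302) lists in mGC1_GFAP against mGC3_CNP, and lost the hypoxia (0.104) and cholesterol synthesis (0.067) lists in mGC2_NES against mGC3_CNP and the Hox list (0.0539) in tumour against NSC. The share of calls with the sign of the NSC line difference was 58.0% for calls of at least 2-fold and 70.5% for the 200 smallest p in mGC1_GFAP against mGC2_NES, against 63.9%. The difference in distance between and within tumour groups remained above 0 by Spearman correlation (0.00345) and over the 1000 probe sets of largest variance (6.88), with an exact permutation p of 0.00357 in each.

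Each named gene was counted once per comparison and setting, with leading list members included and all comparisons pooled. Those called passed again in 2507 cases, no longer passed in 139 and turned sign in 0. Those not called passed in 4 cases and turned sign in 17. The pooled counts hide differences between comparisons. In mGC1_GFAP against mGC3_CNP, 14 of the 20 genes named by the rule lost their call without some array, against 0 of 20 in tumour against NSC. Centring gave Pdgfra 0.0283 in mGC1_GFAP against mGC2_NES and Gfap -0.00585 in mGC2_NES against mGC3_CNP, where a further quantile normalization gave -0.0214 and array weights -0.0668. The covariate gave Cdkn2a 0.0435 in mGC1_GFAP against mGC3_CNP and Cnp 0.0375 in mGC2_NES against mGC3_CNP. Without 1 array, Cnp ran from -0.14 to 0.27 and Gfap from -0.20 to 0.0136 in mGC1_GFAP against mGC3_CNP, Pdgfra from -0.0362 to 0.0126 in mGC1_GFAP against mGC2_NES, and Gfap from -0.12 to 0.14 and Pdgfb from -0.0532 to 0.14 in mGC2_NES against mGC3_CNP. The cause was not tested.

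The replicate numbers of the tumour cultures were not taken as pairs, since only 5 of 9 pairs with the same number had a correlation of deviations over 0.1 (0.0022 to 0.25) and 4 of 9 arrays correlated best with their own number. All 9 of these correlations were above 0 (mean 0.11). That 14 of the 18 between different numbers were below 0 largely follows from this, because the deviations within a group sum to 0. Of the 36 ways to number the arrays, 2, the real one included, gave a mean as high, which leaves a shared source of variation open. With the number as a replicate block the counts were 856 by the F test (651 of the 882 calls among them), 74 for mGC1_GFAP against mGC3_CNP (58 of 106), 1436 for mGC1_GFAP against mGC2_NES (1121 of 1336) and 121 for mGC2_NES against mGC3_CNP (79 of 100, with 56 higher and 65 lower). For tumour against NSC, where the NSC cultures carry no replicate number in the labels, the mouse line shared by both sides served as the block, and 7821 probe sets were called (7659 of the 8004). How far low values lie above background was not measured, and a filter on them gave 108, 1573, 111 and 7172 calls.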

Other observations

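The difference between NSC cultures was planned, but its use as a test of the mouse line as an explanation of the mGC1_GFAP against mGC3_CNP calls was chosen only after the results were seen, as were the tests of both explanations for chromosome 2 and of Prm1 as a transgene transcript.

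Further gene lists fixed beforehand did not pass the list test between tumour and NSC cultures but held members that changed. Of the ERK pathway output list, which follows growth factor signalling, 9 of 17 measured members rose, 4 fell and 4 did not pass the test, against 10 and 4 adjusted over the list alone. Phlda1 (1.47 ± 0.17), Fos (1.52 ± 0.18), the transcription factor gene Etv4 (0.98 ± 0.11) and Myc (0.60 ± 0.07) rose (list adjusted p = 0.0927). Of the stress and immediate early list, 5 of 12 rose and 2 fell, against 5 and 2 adjusted over the list alone, with Nr4a1 (2.49 ± 0.12) and Ier2 (0.86 ± 0.13) rising and Btg2 (-1.33 ± 0.18) falling (list adjusted p = 0.231). Of the TGF-beta and BMP list, 4 of 13 rose and 5 fell, against 4 and 6 adjusted over the list alone. The ligand genes Bmp7 (3.06 ± 0.13) and Bmp4 (1.87 ± 0.21) rose, and the BMP target genes Id1 (-1.93 ± 0.15) and Id4 (-1.49 ± 0.17) fell. Of the Wnt target list, 2 of 9 rose and 3 fell, against 2 and 3 adjusted over the list alone, with Axin2 (-1.12 ± 0.06), Nkd1 (-1.72 ± 0.08) and Znrf3 (-0.81 ± 0.06) falling and Lef1 (2.97 ± 0.21) rising. Of the Hedgehog list, 1 of 6 rose and 3 fell, against 1 and 4 adjusted over the list alone, with Smo (-1.14 ± 0.10), Gli2 (-1.03 ± 0.10) and Gli3 (-0.80 ± 0.19) falling and Hhip (1.16 ± 0.34) rising. Their list adjusted p-values were 0.991, 0.233 and 0.0802. By the reading of low values given above, the differences of Bmp4, Id4, Lef1, Gli2 and Hhip are lower bounds.

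Of the hypoxia list, 4 of 20 rose and 5 fell, against 4 and 6 adjusted over the list alone, with Adm (-3.60 ± 0.43) and Pfkfb4 (-0.87 ± 0.11) falling and Mxi1 (1.03 ± 0.09) and P4ha1 (0.80 ± 0.10) rising. Of the interferon response list, 6 of 21 rose and 6 fell, against 6 and 7 adjusted over the list alone, with Gbp3 (-2.86 ± 0.08) and Ifih1 (-0.82 ± 0.10) falling and Mx2 (1.26 ± 0.17) and Stat2 (0.45 ± 0.07) rising. Of the antigen presentation list, 3 of 8 rose and 2 fell, against 3 and 2 adjusted over the list alone, with the peptide transporter genes Tap1 (0.47 ± 0.09) and Tap2 (0.47 ± 0.10) rising and Nlrc5 (-0.44 ± 0.06) and Tapbp (-0.34 ± 0.08) falling. Of the cholesterol synthesis list, 4 of 16 rose and 2 fell, against 4 and 2 adjusted over the list alone, with Srebf2 (0.51 ± 0.08) and Mvd (0.40 ± 0.09) rising and Idi1 (-0.35 ± 0.09) falling. The list adjusted p-values were 0.751, 0.392, 0.774 and 0.991. The differences of Adm, Pfkfb4, Gbp3, Ifih1, Mx2 and Nlrc5 are lower bounds as well. For Ifih1, Mx2 and Nlrc5 the tumour and the NSC mean both lay below 7.42, so their presence on either side was not shown. The median, the mean and the test differed in sign for the hypoxia, TGF-beta, cholesterol, antigen presentation and Wnt lists here. In the comparisons of tumour groups they did so for the neural stem cell, neuroblast, microglia and endothelial lists (mGC1_GFAP against mGC3_CNP), the astrocyte and Wnt lists (mGC1_GFAP against mGC2_NES) and the astrocyte, endothelial, antigen presentation, Wnt and Hox lists (mGC2_NES against mGC3_CNP).

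Other divisions of the arrays were counted for each comparison. For the F test, 1 of 100 divisions of the 9 tumour arrays, the real one, gave 882 calls and the highest other gave 103. This share under 0.05 argues against chance only if the cultures are independent. For tumour against NSC, 1 of 100 choices of 3 arrays, the real one, gave 8004 calls and the highest other 1546. There the other choices also shuffled the tumour groups, which the real one kept, so this share cannot decide about chance. For the pairwise comparisons, the 6 arrays of both groups were split with the other tumour group kept in the fit. The 10 splits are too few for a share under 0.05, with 106 calls against a highest other of 1 for mGC1_GFAP against mGC3_CNP, 1336 against 1 for mGC1_GFAP against mGC2_NES and 100 against 2 for mGC2_NES against mGC3_CNP.

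Of the 98 genes called between mGC1_GFAP and mGC3_CNP, chromosome 2 (GRCm38.p6) held 25 where 8.55 would be there by share (Fisher's exact test, adjusted p = 4.34e-05 over 60 tests, with neighbouring genes taken as independent). Circular shifts of the gene order put as many on chromosome 2 itself in 162 of 10000 cases (permutation p = 0.0162), and in 956 of 10000 cases 1 of the 20 chromosomes reached as small a p (permutation p = 0.0956), so that a gathering beyond chance was not shown once the choice of chromosome was counted. A copy number difference of the whole chromosome was argued against by the median over its 849 expressed genes, -0.0262 (bootstrap 95% interval -0.0396 to -0.0118), and by 12 genes being higher and 13 lower. Segments of chromosome 2 were not examined, so a copy number difference of a part of it stays open. Sex of the cultures was neither shown nor excluded for the 106 calls. Their median difference stayed at 103% (0.77 to 0.79) with the Y-linked covariate. That covariate is estimated from the spread within mGC1_GFAP and mGC2_NES. A call requires this spread to be small, so the kept median cannot decide. With the covariate the calls dropped to 28, 20 of them among the 106, while the median standard error rose from 0.10 to 0.12. A difference between the mouse lines that precedes the tumours may account for part of the calls, since their median NSC difference was 0.33. The C/tv-a NSC culture also lacked Y-linked transcripts, so that difference is not one of line alone. Of the chromosome 2 genes, 23 of 25 had the same sign in the NSC cultures (92.0%, against 53 of 73 on other chromosomes). With linked genes and 1 NSC culture per line, a line difference, a sex difference and a departure of 1 culture cannot be told apart there. An effect of the cell of origin, which coincides with the line in the tumour cultures, stays open and untested.

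The shift of chromosome 15 in tumour cultures had a median of 0.28 on the log2 scale over 431 expressed genes before the autosomal median was taken off. A chance set of genes was argued against by 0 of 10000 lists of consecutive genes from other chromosomes with a median as high (highest 0.05), and a local cluster by the lowest of 5 consecutive segments over the mean of the 9 cultures, at 0.18. Relative to other autosomes the lowest segment of single cultures lay at 0.14 to 0.22 in 8 of them and at 0.0203 in mGC3_CNP replicate 1, for which a local cluster is not excluded. A gain of the whole chromosome may account for the shift, since the 5 segments lay between 0.18 and 0.34, a range of 0.16, although the shift of 0.29 relative to other autosomes is below the 0.58 (log2) that 3 copies over 2 would give with proportional expression. A lower dose in the NSC cultures in place of a higher one in the tumour cultures, and a biological effect of tumour formation, stay open.

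Prm1, a sperm chromatin gene, read 13.5 in the G/tv-a NSC culture against 7.15 and 7.21 in the other NSC cultures, a difference without a test. Among tumour cultures it was higher in mGC1_GFAP than in mGC3_CNP by at least 0.61 ± 0.07 (limma adjusted p = 0.0135). RNA from germ cells was argued against by the spermatid genes Prm2, Tnp1, Tnp2 and Odf1, whose median difference in that NSC culture was 0.0072 against 6.31 for Prm1. A transcript of the G/tv-a transgene that carries Prm1 sequence may account for it, since the lowest mGC1_GFAP culture lay 0.33 above the highest other tumour culture, and since Gfap, whose promoter drives that transgene, was lower in tumour than in NSC cultures. Whether the transgene holds such sequence was not checked here, and no biological explanation was tested.

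Between mGC1_GFAP and mGC2_NES, chromosome 5 held 96 called genes where 71.2 would be there by share (Fisher's exact test, adjusted p = 0.0494), and 2003 of 10000 circular shifts reached as small a p on 1 of the 20 chromosomes (permutation p = 0.2). Of the 6490 probe sets without a single gene symbol, limma called 45 higher and 5 lower in mGC1_GFAP against mGC3_CNP, 118 and 55 in mGC1_GFAP against mGC2_NES, and 35 and 14 in mGC2_NES against mGC3_CNP.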
